A study of Solanum lycopersicum with 18 samples.

How the data were processed

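Leaf RNA of tomato in 2 materials (Micro-TOM, MT, and Micro-TOM-EX, EX) was measured by RNA sequencing at 0, 2 and 8 h of NaCl treatment, with 3 libraries per group and 18 in all. Plants grew in soil pots in a greenhouse under 16 h of light, total RNA was extracted with Trizol and libraries were read on a BGI500 instrument, per the labels. The salt dose and the genome build were not given in the sources used here. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 were used, without the role of each.

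The authors deposited 1 table of 23808 genes, 761 of them gene models new to the annotation, with FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of each library) rounded to 2 decimals. The same deposited table held the authors' log2 fold change, p-value and q-value of each gene for 9 pairs of groups. No counts were used here. FPKM columns that appear more than once were checked to be identical for all 18 libraries. Symbols, names and positions were taken from the deposited table, and 21978 gene IDs matched a reference table of another assembly. Total FPKM per library was 713442.6 to 778924.4, and 2236 to 3124 genes were listed at 0. Depth was worked out from the spacing of the rounded FPKM values by a search from 12 to 30 M (mega) fragments with a tolerance of 0.15, which gave 17.83 to 20.27 M per library.

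Genes with at least 1 FPKM in at least 3 libraries were tested (18402). As the table held FPKM alone, the fallback written down before the data were examined was used: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 linear model over the 6 groups and all 18 libraries, empirical Bayes moderation with a mean trend, and p-values adjusted by Benjamini and Hochberg in each comparison, with 0.05 as the threshold. The comparisons were 2 h and 8 h against 0 h in each material, Micro-TOM-EX against Micro-TOM at each hour, and the difference between the materials in the 2 h and in the 8 h response. The median standard error of a log2 change was 0.169, and 0.239 for the differences between responses. The test ran on 100 2-fold and 100 4-fold simulated changes, fewer than between hours. It found 52 to 83% and 87 to 100%, with 3 to 14 false calls per comparison. Libraries of the same replicate number were tested for pairing, and only at 0 h between the materials did all 3 numbers correlate above 0.1 (0.48, 0.44 and 0.13). The libraries were treated as unpaired, with the replicate number as a block among the alternatives.

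Gene lists were fixed before the data were examined, 33 of functions and 7 of markers of other cell types and organs, and tested by camera of limma with a preset correlation of 0.01 between genes and at least 5 members. Camera was also run with the correlation estimated from the libraries. Members were counted as called over all genes and, beside it, with p-values adjusted over the list alone, which is given where it differed. The genes named were set by a rule written before the data were examined. It took the 5 largest rises and 5 largest falls in each comparison among genes that passed, reached a mean of 5 FPKM in the higher group, had no overlap of libraries between the groups (not asked of differences between responses) and had a descriptive name. It also took up to 3 members of smallest adjusted p from each list described, and all core salt genes. Genes outside the rule are marked in the text as chosen after their values were seen.

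The alternatives were scaling by median ratios, no filter on low values, a filter of 5 FPKM in 3 libraries, a pseudocount of 0.1, a 2-fold minimum, a fit of the compared groups alone, a replicate block, each library left out in turn, fry in place of camera, and camera with an estimated correlation. Added after the data were seen were the authors' deposited q values, a replicate block within each hour, and a fit without the number 2 libraries of 0 h. Genes of near-identical sequence share reads and were not told apart. The 18 columns of single-sample values beside the FPKM columns were not used here.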

Results

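Gene-level FPKM values (fragments scaled to gene length and library size) were examined for leaves of tomato of 2 materials, named Micro-TOM and Micro-TOM-EX in the labels, before NaCl treatment (0 h) and 2 h and 8 h into it. Micro-TOM is a dwarf tomato cultivar used as a laboratory model, and what distinguishes Micro-TOM-EX was not given. Each of the 6 groups held 3 libraries, 18 in all, and single libraries are named by material (MT for Micro-TOM, EX for Micro-TOM-EX), hour and replicate, as MT0r1. MT0r2 and EX0r2, whose profiles stood apart, are called the r2 pair when left out together. All levels are mean ± SD in FPKM over the 3 libraries of a group. The labels do not say that the 3 libraries of a group came from separate plants, so the p-values measure the spread between samples. Between 15506 and 17343 genes reached 1 FPKM in a library. Correlations of log2 values were 0.965 to 0.993 between libraries of 1 group, 0.95 to 0.983 between the materials at the same hour and 0.667 to 0.832 between hours. Untreated leaves of 2 h or 8 h were not analysed here, so the effect of salt and that of the time of day were not separable in any comparison of hours. Gene positions are those of the deposited table, whose genome build was not given in the sources used here.

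**Figure D1:**
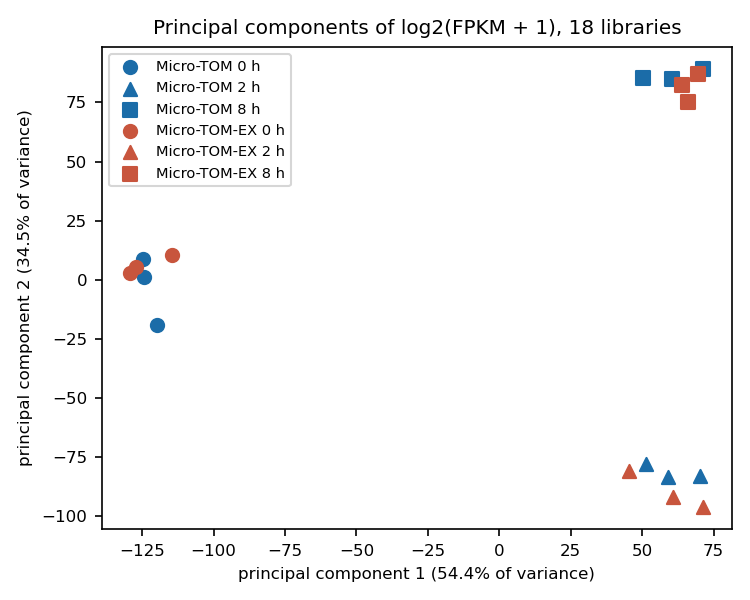
Principal components of the 18 libraries on log2(FPKM + 1), 1 point per library, coloured by material and shaped by hour. The first axis (54.4% of the variance) and the second (34.5%) part the 3 hours.

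The comparison of 2 h with 0 h in Micro-TOM asked which leaf transcripts had changed early after salt was given. The dehydrin TAS14 (gene ID 544056, chromosome 2), a hydrophilic protein induced by abscisic acid and drought, rose from 1.17 ± 0.791 to 2131 ± 255 FPKM (n = 3). The late embryogenesis abundant protein LOC100750252 rose from 0.317 ± 0.172 to 1069 ± 113. Alternative oxidase 1b (LOC543825), which passes electrons past part of the mitochondrial respiratory chain, rose from 0.167 ± 0.0971 to 513 ± 83.9. The EID1-like F-box protein 3 gene LOC101250923 rose from 0.133 ± 0.0451 to 562 ± 35.5. The type 2C protein phosphatase LOC101258071 rose from 0.59 ± 0.295 to 505 ± 26.9. The EXORDIUM-like gene LOC104644303 fell most, from 659 ± 154 to 2.22 ± 0.647. Its relative LOC101250380 fell from 323 ± 119 to 1.59 ± 0.34. The zinc finger gene LOC101256572 (ZAT10-like) fell from 374 ± 196 to 1.88 ± 0.832. The brassinosteroid-regulated BRU1 precursor LOC543637 fell from 286 ± 60.9 to 1.74 ± 0.62 and the NRT1/PTR family transporter LOC101250924 from 348 ± 114 to 2.91 ± 1.37. These 10 genes changed by log2 values between -7.67 and 10.01 (SE 0.23 to 0.93, limma adjusted p from 1.4e-12 to 9.5e-08).

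Of the 18402 genes tested, 13789 changed (5055 higher and 8734 lower). Rescaling the libraries by their median ratios raised the log2 changes by a median of 0.31 and gave 6480 higher and 6814 lower. The authors' deposited table held 7103 and 6541 with q under 0.05, so the majority turned, and gene lists are given with rescaled counts and medians, and p before rescaling.

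Of the 10 late embryogenesis abundant proteins and dehydrins, which protect cells that lose water, 10 rose, 0 fell and 0 did not pass (rescaled 10 and 0, median log2 3.89, camera adjusted p = 0.00014, 0.12 with the correlation between genes estimated from the libraries, then marked estimated). The dehydrin dhn rose from 306 ± 199 to 14770.0 ± 1380.0 FPKM. Of 53 heat shock proteins, chaperones of unfolded protein, 31 rose, 9 fell and 13 did not pass (rescaled 33 and 5, median log2 0.83, adjusted p = 2e-05, 0.12 estimated). Here hsc70 rose from 36.2 ± 10.5 to 2408 ± 77.1 and the small heat shock protein HSP17.4 from 0.07 ± 0.0608 to 31.4 ± 4.9. Of 21 heat stress transcription factors, 13 rose, 4 fell and 4 did not pass (rescaled 14 and 1, median log2 1, adjusted p = 0.0048, 0.061 estimated). LOC104645813 (A-1b-like) went from 0.29 ± 0.165 to 156 ± 41.4. Of 41 NAC transcription factors, 21 rose, 5 fell and 15 did not pass (rescaled 26 and 5, median log2 0.87, adjusted p = 0.0011, 0.06 estimated). LOC101265827 (NAC78) rose from 16.7 ± 1.05 to 152 ± 6.36. Of 39 glutathione S-transferases, detoxifying enzymes, 25 rose, 8 fell and 6 did not pass (26 and 8 adjusted over the list alone, rescaled 28 and 7, median log2 1.17, adjusted p = 0.0011, 0.42 estimated). LOC101256384 went from 100.4 ± 22.4 to 997 ± 130.0 and LOC101253468 from 69 ± 8.11 to 13.6 ± 3.4.

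Lists of sugar, phenolic, jasmonate, clock and proteinase inhibitor genes passed as well. Of 40 genes of trehalose and raffinose synthesis and starch breakdown, 21 rose, 13 fell and 6 did not pass (23 and 13 adjusted over the list alone, rescaled 24 and 8, median log2 0.71, camera adjusted p = 0.014, 0.12 with estimated correlation). Galactinol synthase 2 (GolS2), which starts the raffinose pathway, rose from 2.9 ± 0.576 to 646 ± 32 FPKM. Galactinol synthase 1 (GolS-1) was listed at 0 in all 3 libraries of 0 h and at 146 ± 26.6 FPKM at 2 h. Of 62 phenylpropanoid and flavonoid genes, 29 rose, 16 fell and 17 did not pass (rescaled 30 and 13, median log2 0.38, adjusted p = 0.0066, 0.46 estimated). The trans-cinnamate 4-monooxygenase LOC101244196 went from 7.77 ± 2.97 to 348 ± 30.1 and the leucoanthocyanidin dioxygenase-like LOC101248924 from 0.03 ± 0.052 to 284 ± 67. Of 36 jasmonate synthesis genes and JAZ repressors, 21 rose, 11 fell and 4 did not pass (rescaled 22 and 9, median log2 1.19, adjusted p = 0.019, 0.39 estimated). Allene oxide cyclase (AOC), an enzyme of jasmonate synthesis, rose from 31.6 ± 15.8 to 2503 ± 267. JA2, in the list by name only, rose from 27.7 ± 3.49 to 1084 ± 80.8. Of 27 circadian clock genes, 13 rose, 9 fell and 5 did not pass (13 and 10 adjusted over the list alone, rescaled 15 and 6, median log2 0.55, adjusted p = 0.011, 0.12 estimated). The GIGANTEA-like LOC101258346 went from 0.0767 ± 0.0208 to 51.4 ± 4.75 and APRR1 (LOC101259163) from 11.4 ± 1.25 to 234 ± 17.8. Of 23 wound-induced proteinase inhibitors, 7 rose, 2 fell and 14 did not pass (6 and 1 adjusted over the list alone, rescaled 10 and 1, median log2 0.58, adjusted p = 0.045, 0.63 estimated). ARPI went from 0.433 ± 0.379 to 54.9 ± 16.7. After rescaling the jasmonate list (adjusted p = 0.093) and the proteinase inhibitors (0.17) no longer passed, and the latter had adjusted p = 0.056 to 0.093 without any 1 of 4 libraries.

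Most members of the plastid lists fell. Of 46 plastid-type ribosomal proteins, 0 rose, 44 fell and 2 did not pass (rescaled 1 and 42, median log2 -1.51, camera adjusted p = 8.1e-07, 0.46 with estimated correlation). LOC101244648 (50S L29) fell from 115 ± 4.34 to 25.9 ± 1.46 FPKM and LOC101258952 (30S protein 3) from 106 ± 11.4 to 4.39 ± 1.95. Of 56 photosystem and light-harvesting proteins, 2 rose, 44 fell and 10 did not pass (2 and 45 adjusted over the list alone, rescaled 2 and 41, median log2 -1.69, adjusted p = 0.0032, 0.75 estimated). The photosystem II gene psbY (LOC101259494) fell from 1891 ± 181 to 194 ± 67.2. The 2 photosystem members that rose, named after their values were seen, were the light-harvesting genes LOC101267774 (2.53 log2) and Cab-1B (1.84). Likewise, the 5 NAC genes that fell were LOC101246188, LOC101257530, LOC101257801, LOC101263872 and LOC101268061, the 4 heat stress factors LOC101243963, LOC101258637, LOC101259859 and HsfA1a, and the 2 proteinase inhibitors LOC101249175 and ER1. Adjusted p was, for Cab-1B 0.05 without MT0r1, for LOC101258637 0.067 without MT0r1, for HsfA1a 0.062 to 0.14 without any 1 of 4 libraries. It was, for ER1 0.072 to 0.12 without any 1 of 4 libraries, for LOC101246188 0.061 without MT0r1, 0.069 without MT2r1. After rescaling, HsfA1a (0.08 log2), LOC101243963, LOC101258637 and ER1 did not pass. With a block within each hour LOC101246188 (0.089), LOC101263872 (0.092), HsfA1a (0.11) and ER1 (0.38) did not, nor LOC101258637 (0.057) and HsfA1a (0.13) in a fit of the 2 groups alone.

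The other lists did not pass camera at 2 h in Micro-TOM (adjusted p from 0.071 to 0.89) and had members on both sides, given here as higher and lower of all tested. Na and K transport held 11 and 18 of 35. Abscisic acid genes held 8 and 11 of 24, CBL and CIPK calcium signalling 11 and 9 of 33, proline metabolism 2 and 3 of 10 (rescaled, 3 and 3) and clade A phosphatases 5 and 4 of 11. Antioxidant enzymes held 9 and 11 of 34 (rescaled, 11 and 11). Class III peroxidases held 11 and 8 of 26, polyamine synthesis 5 and 3 of 11. Ethylene synthesis and reception held 14 and 9 of 35 and AP2/ERF factors 37 and 31 of 83. MYB factors held 22 and 18 of 53, WRKY factors 18 and 21 of 52 (rescaled, 21 and 18), auxin response 17 and 42 of 81. Gibberellin and cytokinin metabolism held 10 and 8 of 24 and cell wall enzymes 36 and 54 of 121. Aquaporins held 9 and 7 of 26, pathogenesis-related proteins 24 and 24 of 77 (rescaled, 28 and 18) and DNA replication and histones 16 and 17 of 54 (rescaled, 22 and 13). Cytosolic ribosomal proteins held 23 and 62 of 208 (rescaled, 81 and 20) and proteasome subunits 5 and 16 of 37 (rescaled, 14 and 7), so their direction turned with the rescaling. The median and the mean log2 change differed in sign for the CBL and CIPK, pathogenesis-related and histone lists. Markers of other leaf cell types and organs did not pass either (adjusted p from 0.17 to 0.92). The lowest adjusted p of a marker list in any comparison was 0.094 (flower and anther, between the materials at 2 h).

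Of the 7 core salt genes, the 9-cis-epoxycarotenoid dioxygenase NCED5 (LOC100316877), which starts abscisic acid synthesis, rose from 4.87 ± 0.706 to 12.1 ± 1.53 FPKM and the sodium transporter HKT1;2 from 6.22 ± 1.51 to 15.8 ± 2.6, in addition to TAS14 (10.01 log2). The pyrroline-5-carboxylate synthase LOC101250107, of the enzyme that starts proline synthesis, fell from 4.45 ± 0.428 to 1.41 ± 0.49, and the sodium/hydrogen exchanger LOC101263995 from 2.23 ± 0.182 to 1.21 ± 0.173. The other pyrroline-5-carboxylate synthases did not pass: LOC101244293 was at 11.3 ± 3.24 and 10.1 ± 1.89 FPKM, PRO2 at 35.2 ± 0.423 and 35.8 ± 2.67. PRO2 passed as higher after rescaling (adjusted p = 0.0049).

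The comparison of 8 h with 0 h in Micro-TOM asked what the leaf transcripts were after a longer time in salt. TAS14 reached 9287 ± 1450.0 FPKM from 1.17 ± 0.791 at 0 h (n = 3). LE25 rose from 0.22 ± 0.381 to 1330.0 ± 360.0. The late embryogenesis abundant protein LOC100750252 rose from 0.317 ± 0.172 to 1209 ± 279. The aldo-keto reductase LOC101250974 rose from 0.48 ± 0.184 to 1158 ± 202 and the endoglucanase inhibitor Xegip, which blocks a fungal cell wall enzyme, from 1.19 ± 0.689 to 1437 ± 448. LOC104644303 (EXORDIUM-like) fell from 659 ± 154 to 0.723 ± 0.136. LOC101250380 fell from 323 ± 119 to 0.483 ± 0.2 and the zinc finger gene LOC101256572 from 374 ± 196 to 0.187 ± 0.196. The auxin-binding protein gene LOC101250583 (ABP19a) fell from 602 ± 194 to 1.52 ± 1.48 and LOC101258270 (CCR4-associated factor 1 homolog 9) from 576 ± 50 to 2.52 ± 0.712. Log2 changes of these 10 genes lay between -8.56 and 12.13 (SE 0.22 to 0.96, limma adjusted p from 2.3e-13 to 1.2e-07). Among all genes, 12990 changed, 6816 higher and 6174 lower.

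All 10 late embryogenesis abundant proteins and dehydrins rose (median log2 4.03, camera adjusted p = 0.00056, 0.28 with estimated correlation). Of 37 proteasome subunits, the machinery of protein breakdown, 30 rose, 1 fell and 6 did not pass (median log2 0.70, adjusted p = 2e-05, 0.28 estimated). LOC101250370 (alpha type-6) went from 74.2 ± 3.15 to 217 ± 20.3. Of 27 clock genes, 20 rose, 4 fell and 3 did not pass (median log2 1.33, adjusted p = 0.00055, 0.084 estimated). GIGANTEA (LOC101255788) rose from 0.513 ± 0.242 to 81.4 ± 4.57 and its homologue LOC101258346 from 0.0767 ± 0.0208 to 145 ± 3.36. The 4 clock genes that fell encode morning factors of the clock and their relatives, LHY (LOC101261662, -4.50 log2), REVEILLE 8 (LOC101253545, -3.45), REVEILLE 1 (LOC101261079, -3.43) and REVEILLE 7 (LOC101255972, -3.40), named after their values were seen. Of 53 heat shock proteins, 35 rose, 5 fell and 13 did not pass (35 and 7 adjusted over the list alone, median log2 0.75, adjusted p = 0.00055, 0.28 estimated). LOC100736525 went from 27.6 ± 12 to 1606 ± 204. Of 21 heat stress factors, 14 rose, 1 fell and 6 did not pass (median log2 0.67, adjusted p = 0.0066, 0.084 estimated). Of 23 proteinase inhibitors, 17 rose, 0 fell and 6 did not pass (17 and 1 adjusted over the list alone, median log2 2.51, adjusted p = 0.0051, 0.7 estimated). ARPI went from 0.433 ± 0.379 to 137 ± 58.3. Of 39 glutathione S-transferases, 26 rose, 10 fell and 3 did not pass (median log2 1.19, adjusted p = 0.042, 0.88 estimated).

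Most members of the photosystem and ribosomal lists fell at 8 h. Of 56 photosystem proteins, 2 rose, 45 fell and 9 did not pass (2 and 46 adjusted over the list alone, median log2 -1.95, camera adjusted p = 1.2e-06, 0.88 with estimated correlation). The subunit psbS, which lets plants dissipate excess light as heat, fell from 575 ± 178 to 13.7 ± 8.51 FPKM and LOC101259227 (PsbP family) from 81.2 ± 15.9 to 7 ± 3.51. Of 46 plastid-type ribosomal proteins, 2 rose, 38 fell and 6 did not pass (2 and 39 adjusted over the list alone, median log2 -1.29, adjusted p = 3e-07, 0.7 estimated). Of 208 cytosolic ribosomal proteins, 7 rose, 116 fell and 85 did not pass (7 and 110 adjusted over the list alone, median log2 -0.41, adjusted p = 3.9e-05, 0.91 estimated). LOC101245873 (60S L5) went from 126 ± 4.01 to 47.2 ± 0.19. Of 83 AP2/ERF factors, 23 rose, 40 fell and 20 did not pass (median log2 -0.35, adjusted p = 0.048, 0.56 estimated). LOC101249309 fell from 613 ± 24.4 to 36.1 ± 2.2, and the ABR1-like LOC101251084 rose from 0.53 ± 0.141 to 289 ± 99.3. The AP2/ERF list had adjusted p = 0.082 after rescaling and 0.078 without MT0r2, 0.076 without MT8r1, and without the r2 pair it had 0.077 and the glutathione S-transferases 0.068.

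Members that moved against their list, named after their values were seen, were LOC101267774 and Cab-1B (photosystem), LOC101245144 and LOC101259205 (plastid-type ribosome), LOC101258384 (proteasome), LOC101259859 (heat stress factor) and LOC101254866, LOC101255395, LOC101256232, LOC101263239 and LOC101264183 (heat shock). Adjusted p was, for Cab-1B 0.086 to 0.2 without any 1 of 4 libraries, for LOC101259205 0.053 without MT0r1, 0.075 without MT8r2, for LOC101254866 0.06 to 0.17 without any 1 of 3 libraries. It was, for LOC101256232 0.071 without MT8r3. With a block within each hour Cab-1B (0.14) and LOC101254866 (0.25) did not pass, nor Cab-1B without a filter (0.061) and with 2 groups alone (0.092), and LOC101254866 without the r2 pair (0.18). Of the core salt genes beside TAS14, the pyrroline-5-carboxylate synthases LOC101244293 and PRO2 rose from 11.3 ± 3.24 to 43.5 ± 8.95 and from 35.2 ± 0.423 to 45 ± 2.62 FPKM. NCED5 (LOC100316877) fell from 4.87 ± 0.706 to 0.293 ± 0.0764 and HKT1;2 from 6.22 ± 1.51 to 0.987 ± 0.49. LOC101250107 fell from 4.45 ± 0.428 to 3.16 ± 0.54 (adjusted p = 0.035, and 0.085 to 0.15 without any 1 of 3 libraries, 0.051 to 0.29 with a pseudocount of 0.1, with 2 groups alone, without the r2 pair and with a block within each hour), and LOC101263995 stood at 2.23 ± 0.182 and 2.1 ± 0.225 without passing.

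The same question was asked in Micro-TOM-EX at 2 h. The leucoanthocyanidin dioxygenase-like gene LOC101248924, of the anthocyanin pathway, rose from 0.58 ± 0.845 to 422 ± 158 FPKM (n = 3). Its relative LOC101248628 rose from 0.727 ± 1.13 to 288 ± 127. Alternative oxidase 1b (LOC543825) rose from 1.44 ± 1.69 to 550.2 ± 43.2. The arogenate dehydrogenase LOC101259361, of tyrosine synthesis, rose from 0.32 ± 0.148 to 337 ± 22.7 and the hexose transporter ht2 from 1.87 ± 1.83 to 497 ± 22.3. The aldolase SlFBA6 fell from 535 ± 138 to 12.2 ± 21.2 and was listed at 0 in EX 2 h replicates 2 and 3. LOC104644303 (EXORDIUM-like) fell from 341 ± 29 to 1.49 ± 0.878. The GAST1-like LOC101252867 fell from 335 ± 78.1 to 2.4 ± 2.75, LOC101250924 from 272 ± 81.5 to 1.47 ± 0.462 and LOC101256572 from 366 ± 85.5 to 3.15 ± 0.939. These 10 changed by log2 values between -7.29 and 8.13 (SE 0.23 to 0.96, limma adjusted p from 1.7e-12 to 4e-06). In all 13968 genes changed, 4919 higher and 9049 lower. Rescaling raised the log2 changes by a median of 0.39 and gave 6694 higher and 6849 lower, and the authors' table held 6707 and 6326, the majority turned, so rescaled list values are given again.

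Of 53 heat shock proteins, 30 rose, 13 fell and 10 did not pass (rescaled 32 and 6, median log2 0.96, camera adjusted p = 5.3e-05, 0.19 with estimated correlation). HSP17.4 went from 0.103 ± 0.105 to 61.3 ± 6.39 FPKM and HSP90 from 0.657 ± 0.352 to 90 ± 21.7. Of 10 late embryogenesis abundant proteins and dehydrins, 8 rose, 0 fell and 2 did not pass (9 and 0 adjusted over the list alone, rescaled 9 and 0, median log2 4.17, adjusted p = 0.0013, 0.26 estimated). dhn went from 203 ± 182 to 11830.0 ± 2700.0. Of 62 phenylpropanoid and flavonoid genes, 33 rose, 17 fell and 12 did not pass (rescaled 35 and 16, median log2 1.08, adjusted p = 0.003, 0.44 estimated). Of 39 glutathione S-transferases, 24 rose, 8 fell and 7 did not pass (rescaled 26 and 8, median log2 1, adjusted p = 0.003, 0.44 estimated). Of 36 jasmonate genes, 19 rose, 10 fell and 7 did not pass (20 and 10 adjusted over the list alone, rescaled 22 and 10, median log2 1.09, adjusted p = 0.0084, 0.31 estimated). Allene oxide synthase (aos) went from 3.16 ± 0.942 to 653 ± 127. Of 21 heat stress factors, 11 rose, 4 fell and 6 did not pass (rescaled 13 and 2, median log2 0.89, adjusted p = 0.0084, 0.1 estimated). Of 41 NAC factors, 17 rose, 8 fell and 16 did not pass (rescaled 23 and 6, median log2 0.60, adjusted p = 0.0084, 0.1 estimated). LOC101267632 (B-2b) rose from 1.98 ± 0.51 to 117 ± 7.44.

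Of 83 AP2/ERF factors, 35 rose, 30 fell and 18 did not pass (rescaled 41 and 24, median log2 0.49, camera adjusted p = 0.02, 0.31 with estimated correlation). LOC101251084 (ABR1-like) rose from 1.08 ± 0.883 to 248 ± 26.3 FPKM, and LOC104645451 was listed at 0 in all 3 libraries of 0 h and stood at 43.7 ± 7.33 at 2 h. Of 40 trehalose, raffinose and starch genes, 17 rose, 11 fell and 12 did not pass (rescaled 23 and 10, median log2 0.65, adjusted p = 0.032, 0.19 estimated). GolS2 went from 3.62 ± 1.06 to 276 ± 81. Of 11 clade A type 2C protein phosphatases, which restrain abscisic acid signalling, 6 rose, 4 fell and 1 did not pass (rescaled 6 and 2, median log2 1.57, adjusted p = 0.049, 0.31 estimated). LOC101261835 rose from 18.9 ± 3.07 to 218 ± 11, while the 4 that fell, named after their values were seen, were LOC101253040, LOC101258862, LOC101260150 and LOC101265524. After rescaling the phosphatases (adjusted p = 0.099), the jasmonate list (0.064), AP2/ERF (0.1) and the sugar list (0.06) no longer passed, and the phosphatases had 0.051 without EX0r3 and 0.056 without the r2 pair, and 0.056 in the blocked fit. The 208 cytosolic ribosomal proteins, 33 higher and 63 lower, did not pass (adjusted p = 0.36), and after rescaling, with 107 and 18, they passed (0.0086), so their direction turned. Without the r2 pair they (0.021) and the proteinase inhibitors (0.021) passed. After rescaling LOC101253040 and LOC101258862 did not pass (adjusted p = 0.093 and 0.13), nor did the first with a block within each hour (0.098).

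Of 46 plastid-type ribosomal proteins, 1 rose, 42 fell and 3 did not pass (rescaled 2 and 42, median log2 -1.59, camera adjusted p = 1.7e-06, 0.52 with estimated correlation). Of 56 photosystem proteins, 2 rose, 45 fell and 9 did not pass (rescaled 2 and 42, median log2 -1.49, adjusted p = 0.0084, 0.84 estimated). psbY (LOC101259494) went from 2250.0 ± 218 to 307 ± 174. Against their lists rose LOC101267774, Cab-1B (photosystem) and LOC101260032 (50S HLP, mitochondrial by its name), and fell the heat stress factors LOC101250985, LOC101258637, LOC101259859 and HsfA1a, all named after their values were seen. Adjusted p was, for Cab-1B 0.053 to 0.14 without any 1 of 5 libraries, for LOC101260032 0.062 without EX0r1, for LOC101258637 0.05 without EX0r1, 0.064 without EX2r2. After rescaling HsfA1a stood at 0.04 log2 and LOC101258637 did not pass, nor LOC101260032 in a fit of the 2 groups alone (0.068).

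Of the core salt genes, TAS14 rose from 52.9 ± 86.2 to 1559 ± 443 FPKM, and EX0r2 alone held 152.43 against 2.15 and 4.14. LOC101250107 fell from 4.88 ± 0.191 to 2.11 ± 0.386 and LOC101263995 from 2.24 ± 0.248 to 0.883 ± 0.204. NCED5 (LOC100316877) went from 8.93 ± 1.23 to 11.4 ± 0.918 with adjusted p = 0.033, and 0.072 to 0.17 without any 1 of 3 libraries, 0.085 with a pseudocount of 0.1 and 0.074 with 2 groups alone. HKT1;2 went from 7.17 ± 1.4 to 12.3 ± 5.26 with adjusted p = 0.048, and 0.093 to 0.26 without any 1 of 4 libraries, 0.067 to 0.12 without a filter, with a pseudocount of 0.1, with 2 groups alone and with a block within each hour. LOC101244293 stood at 17.5 ± 5.56 and 12.5 ± 1.24 and PRO2 at 35.5 ± 0.549 and 32.1 ± 5.52, and neither passed, while adjusted p was 0.036 without EX0r1 for LOC101244293 and 0.025 without EX2r1 for PRO2 as lower. After rescaling PRO2 passed as higher (0.27 log2, adjusted p = 0.027).

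At 8 h in Micro-TOM-EX, TAS14 rose from 52.9 ± 86.2 to 9554 ± 2280.0 FPKM (n = 3), LOC100750252 from 12.3 ± 20.2 to 1802 ± 699. LE25 rose from 19.5 ± 33 to 1796 ± 318 and LOC101250974 from 16.8 ± 28.1 to 1603 ± 210.0. The wide SD of these at 0 h came from EX0r2, which held 57.56 FPKM of LE25 against 0.28 and 0.54. The ribonuclease RNALE rose from 1.38 ± 1.97 to 521 ± 117. The zinc finger gene LOC101256572 fell from 366 ± 85.5 to 0.433 ± 0.361, ABP19a (LOC101250583) from 430.4 ± 70.1 to 0.777 ± 0.44. The GAST1-like LOC101252867 fell from 335 ± 78.1 to 0.85 ± 0.161 and the EXORDIUM-like LOC101250380 and LOC104644303 from 257 ± 29.4 to 0.543 ± 0.254 and from 341 ± 29 to 1.19 ± 0.248. These 10 changed by log2 values between -8.00 and 9.43 (SE 0.23 to 0.96, limma adjusted p from 9.5e-13 to 8.4e-07). In all 13115 genes changed, 6527 higher and 6588 lower (6653 and 6403 after rescaling, the majority turned).

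Of 56 photosystem proteins, 1 rose, 48 fell and 7 did not pass (1 and 49 adjusted over the list alone, median log2 -2.64, camera adjusted p = 2e-07, 0.71 with estimated correlation). psbS went from 759.6 ± 57.4 to 13.5 ± 10.7 FPKM. Of 46 plastid-type ribosomal proteins, 3 rose, 39 fell and 4 did not pass (median log2 -1.54, adjusted p = 2.1e-07, 0.71 estimated). Of 208 cytosolic ribosomal proteins, 6 rose, 117 fell and 85 did not pass (6 and 115 adjusted over the list alone, median log2 -0.39, adjusted p = 0.00013, 0.85 estimated). Of 81 auxin response genes, 20 rose, 40 fell and 21 did not pass (20 and 41 adjusted over the list alone, median log2 -0.61, adjusted p = 0.049, 0.71 estimated). Auxin response factor 4 (ARF4) fell from 39.9 ± 4.31 to 1.97 ± 0.437. The auxin list had adjusted p = 0.06 without EX0r3, 0.071 without EX8r1, and 0.055 with the replicate number as a block.

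All 10 late embryogenesis abundant proteins and dehydrins rose (median log2 4.67, camera adjusted p = 0.00022, 0.31 with estimated correlation). Of 37 proteasome subunits, 28 rose, 1 fell and 8 did not pass (median log2 0.81, adjusted p = 7.4e-06, 0.36 estimated). Of 27 clock genes, 18 rose, 5 fell and 4 did not pass (median log2 1.18, adjusted p = 0.0017, 0.13 estimated). The GIGANTEA-like LOC101258346 rose from 0.353 ± 0.371 to 145 ± 14.3, and the 5 that fell, named after their values were seen, were LHY (LOC101261662, -5.17 log2), REVEILLE 7 (LOC101255972, -4.39), REVEILLE 1 (LOC101261079), REVEILLE 8 (LOC101253545) and APRR5 (LOC101256648). Of 21 heat stress factors, 13 rose, 2 fell and 6 did not pass (median log2 0.81, adjusted p = 0.0053, 0.13 estimated). Of 53 heat shock proteins, 29 rose, 9 fell and 15 did not pass (median log2 0.46, adjusted p = 0.008, 0.52 estimated). Of 23 proteinase inhibitors, 16 rose, 0 fell and 7 did not pass (median log2 2.35, adjusted p = 0.008, 0.71 estimated). ARPI went from 0.567 ± 0.654 to 117 ± 93.3. Of 39 glutathione S-transferases, 27 rose, 10 fell and 2 did not pass (median log2 1.37, adjusted p = 0.012, 0.71 estimated).

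Against their lists moved LOC101267774 (photosystem), rps16, LOC101245144 and LOC101250551 (small-subunit ribosomal proteins, the last mitochondrial by its name), LOC101258384 (proteasome) and LOC101259859 and LOC101266046 (heat stress factors), named after their values were seen. Adjusted p was, for rps16 0.087 without EX0r1, 0.074 without EX8r1, for LOC101250551 0.078 to 0.22 without any 1 of 4 libraries, for LOC101266046 0.051 without EX8r1. In a fit of the 2 groups alone rps16 (0.096) and LOC101250551 (0.12) did not pass. Of the other core salt genes, LOC101244293 rose from 17.5 ± 5.56 to 50.3 ± 7.64 FPKM and PRO2 from 35.5 ± 0.549 to 45.5 ± 2.37, and NCED5 (LOC100316877) fell from 8.93 ± 1.23 to 0.62 ± 0.0458 and HKT1;2 from 7.17 ± 1.4 to 1.01 ± 0.55. LOC101250107 stood at 4.88 ± 0.191 and 3.92 ± 0.691 and LOC101263995 at 2.24 ± 0.248 and 2.6 ± 0.897, and neither passed.

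**Figure D2:**
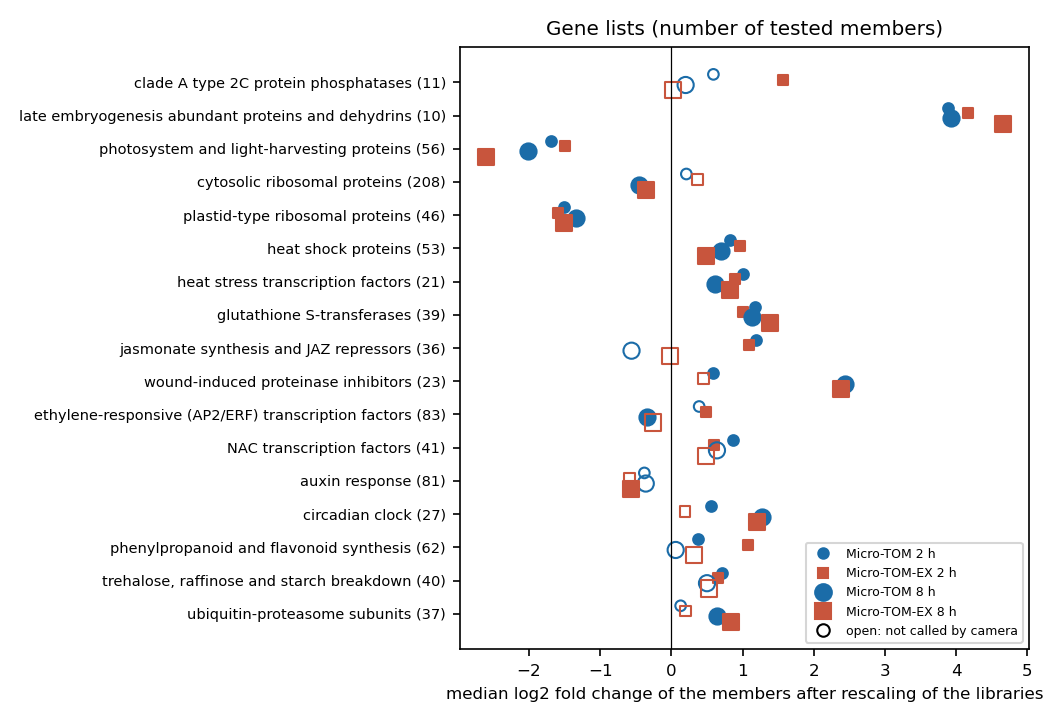
Rescaled median log2 change of 17 gene lists in the 4 comparisons of hours, filled where camera passed. Late embryogenesis abundant proteins lie highest, at 3.89 (Micro-TOM 2 h) to 4.66 (Micro-TOM-EX 8 h).

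The authors' deposited table held 13644 and 13201 genes with q under 0.05 for 2 h and 8 h in Micro-TOM, and 13033 and 13219 in Micro-TOM-EX. Across the 18402 genes the responses of the 2 materials ran close together. At 2 h Pearson's r across genes was 0.939 (Spearman's rho 0.929, slope 0.965) and at 8 h 0.959 (rho 0.947, slope 0.96), where genes are not independent replicates. At 2 h 12138 genes changed in the same direction in both materials, 4210 higher against 1351.2 for independent lists and 7928 lower against 4294.9, and 101 changed in opposite directions. At 8 h the same direction was shared by 11511 genes, 5912 higher against 2417.6 and 5599 lower against 2210.3, and 32 were opposite.

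**Figure D3:**
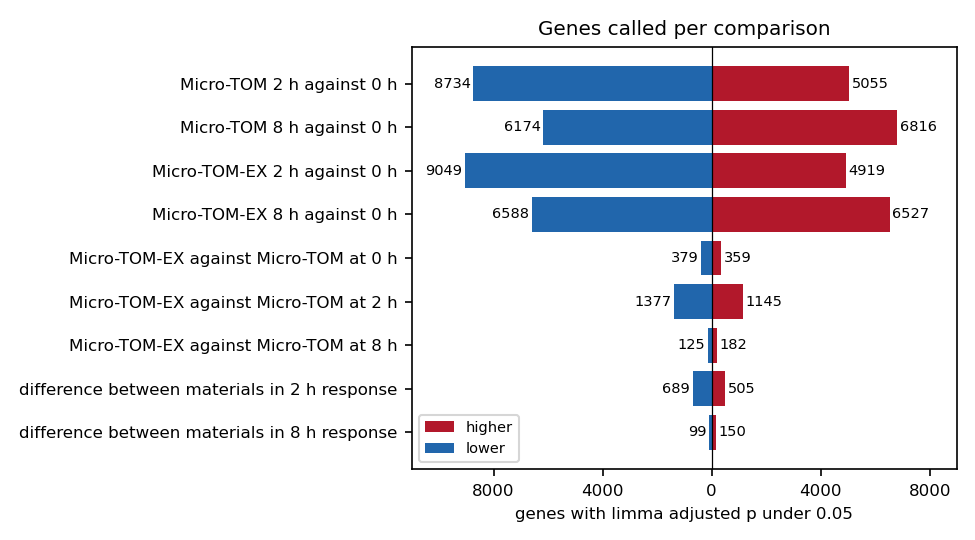
Number of genes with limma adjusted p under 0.05 in each comparison, higher to the right and lower to the left of 0.

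The comparison of Micro-TOM-EX with Micro-TOM at 0 h asked how the materials differed before salt. Non-symbiotic hemoglobin class 1 (Glb1, gene ID 100736435, chromosome 7), an oxygen-binding protein, was higher in EX at 160.2 ± 30.2 against 20.8 ± 35.5 FPKM (n = 3), and the MT libraries held 0.24, 61.8 and 0.24. The ripening-regulated gene DDTFR18 (chromosome 4) stood at 19.7 ± 3.18 against 2.39 ± 0.704. The transcription factor IBH1 (LOC109119046, chromosome 12) stood at 6.71 ± 2.01 against 0.623 ± 0.201. The calcium-dependent protein kinase LOC101255379 (chromosome 12) stood at 6.09 ± 2.17 against 0.76 ± 0.711 and the kirola-like LOC101264616 at 147 ± 121 against 31 ± 14.2. Lower in EX was the small GTPase gene LOC101262189 (RABH1e-like, chromosome 3) at 0.997 ± 0.376 against 71.8 ± 19.4. The lipid transfer gene LOC101246488 stood at 0.593 ± 0.482 against 24.3 ± 7.57 and the cellulose synthase-like D3 gene LOC101247596 at 7.39 ± 2.74 against 125 ± 102. The transporter LOC101254912 (NRT1/PTR family 8.1) stood at 0.423 ± 0.138 against 9.82 ± 2.33. The glucosyltransferase LOC101248405 (chromosome 7), beside Glb1 on the chromosome, was listed at 0 in all 3 EX libraries and at 6.74, 3.84 and 5.3 in MT. Fitted log2 differences of the other 9 lay between -5.17 and 5.12 (SE 0.14 to 1, limma adjusted p from 8.3e-10 to 0.018). Fitted to the 6 libraries of 0 h alone, Glb1 (0.23), LOC101255379 (0.083), LOC101264616 (0.23) and LOC101247596 (0.086) did not pass by adjusted p, and LOC101264616 had 0.061 to 0.083 without any 1 of 3 libraries.

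In all 738 genes differed, 359 higher and 379 lower in Micro-TOM-EX, and the authors' deposited table held 872 with q under 0.05, 318 higher and 554 lower. The split was 302 and 428 after rescaling and turned to 361 and 278 without EX0r1. With the replicate number as a block the count was 782, without EX0r3 it was 420, without the r2 pair 571, and 104 in a fit of the 0 h libraries alone. Of 54 DNA replication and histone genes, 2 were higher, 0 lower and 52 did not pass (median log2 0.31, camera adjusted p = 0.002, 0.99 with estimated correlation). These were H2B-3 at 88.1 ± 16.5 against 60.7 ± 2.47 FPKM and LOC101268556 (histone H3.2). Of 52 WRKY factors, 0 were higher, 3 were lower and 49 did not pass (0 and 7 adjusted over the list alone, median log2 -0.15, adjusted p = 0.002, 0.99 estimated). They were LOC101258194 (WRKY 22-like) at 11.4 ± 3.59 against 30.4 ± 9.98, SlWRKY2 and LOC101246812 (WRKY 40). The histone list had adjusted p = 0.11 without MT0r1, 0.37 without EX0r2, and 1 list passed without MT0r1, 8 without MT0r2 and 4 without EX0r1. Leaving out 1 library ended the call of each of these 5 genes. Adjusted p was, for H2B-3 0.05 without MT0r1, 0.052 without EX0r2, for LOC101268556 0.058 to 0.091 without any 1 of 4 libraries, for LOC101258194 0.063 without EX0r3. It was, for SlWRKY2 0.055 to 0.098 without any 1 of 4 libraries, for LOC101246812 0.057 to 0.12 without any 1 of 3 libraries. None of the 5 passed in a fit of the 0 h libraries alone (adjusted p from 0.068 to 0.35) or without the r2 pair (from 0.056 to 0.1), nor LOC101268556 with a pseudocount of 0.1 (0.097) and LOC101246812 without a filter (0.05). In the blocked fit 3 lists passed, the third being the cytosolic ribosomal proteins (adjusted p = 0.0099), and with a block within each hour LOC101246812 did not pass (0.056). After rescaling the photosystem proteins passed (0.0071, 0.061 before), as they did without the r2 pair (0.00022) with the heat shock proteins (0.043) and the core salt genes (0.043).

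Of the core salt genes, NCED5 (LOC100316877) was higher in Micro-TOM-EX at 0 h, 8.93 ± 1.23 against 4.87 ± 0.706 FPKM, by 0.76 log2 (adjusted p = 0.0029, and 0.11 in a fit of the 0 h libraries alone). TAS14 stood at 52.9 ± 86.2 against 1.17 ± 0.791 and did not pass (2.72 log2 and adjusted p = 0.14, 0.97 and 0.16 without EX0r2, 3.77 and 0.03 without EX0r1). The other log2 differences, none of which passed, were 0.59 for LOC101244293, 0.11 for LOC101250107, 0.19 for HKT1;2, 0.01 for PRO2, 0.00 for LOC101263995.

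At 2 h the question was how the materials differed early in salt. Glb1 was again higher in Micro-TOM-EX, 56.4 ± 18.3 against 0.27 ± 0.254 FPKM (n = 3), and the STAY-GREEN-like gene LOC101258237 (chromosome 12), of a family that takes part in chlorophyll breakdown, stood at 48.5 ± 4.17 against 0.43 ± 0.06. The cellulose synthase-like E6 gene LOC101268453 stood at 44.4 ± 6.1 against 0.717 ± 0.103. The hydroxylase LOC101244810 (chromosome 9) stood at 33.5 ± 12 against 0.437 ± 0.0764 and the Avr9/Cf-9 rapidly elicited gene CMPG1, of a family of defence-related ubiquitin ligases, at 35 ± 8.01 against 0.883 ± 0.0462. Lower in EX was an ATP-citrate synthase gene LOC101258745 at 0.0133 ± 0.0231 against 14.7 ± 1.97. LOC101262189 (RABH1e-like) stood at 1.86 ± 0.392 against 38.5 ± 3.89 and the receptor-like kinase LOC101268564 at 5.04 ± 3.13 against 55.2 ± 15.7. The chloroplast superoxide dismutase SODCP.2, which removes superoxide, stood at 1.12 ± 0.293 against 30.7 ± 25.3. MT2r1 held 2.08 FPKM of it against 40.11 and 49.93 in replicates 2 and 3. The MADS-box gene LOC101244319 stood at 2.02 ± 1.29 against 22.4 ± 7.94. These 10 log2 differences lay between -3.95 and 5.46 (SE 0.12 to 1, limma adjusted p from 4.8e-12 to 0.011). SODCP.2 had adjusted p = 0.052 without MT2r2, 0.056 without MT2r3, and 0.086 in a fit of the 2 h libraries alone.

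In all 2522 genes differed, 1145 higher and 1377 lower in Micro-TOM-EX. After rescaling 1483 were higher and 1329 lower, so the majority turned. The authors' deposited table held 3011 with q under 0.05. The count was 1259 without MT2r1 and 1357 without EX2r3. Of 208 cytosolic ribosomal proteins, 6 were higher, 1 lower and 201 did not pass (3 and 1 adjusted over the list alone, 10 and 2 after rescaling, median log2 0.16, camera adjusted p = 0.00074, 1 with estimated correlation). The P3-like LOC101246068 stood at 263 ± 40.7 against 76.3 ± 6.77 FPKM, and the lower gene was LOC101244058 (L18a-like) at 32.1 ± 2.05 against 46.1 ± 2.43. Of 56 photosystem proteins none passed limma (0 adjusted over the list alone), 5 had an unadjusted p under 0.05 and 6 a q under 0.05 in the authors' deposited table, while the median log2 difference was 0.60 (adjusted p = 0.007, 1 estimated). The photosystem list had adjusted p = 0.19 without MT2r1, 0.79 without EX2r1. The ribosomal list had 0.11 without MT2r1, 0.22 without EX2r2, and 0, 1 and 1 lists passed without MT2r1, EX2r1 and EX2r2. None of the 7 core salt genes passed limma, with -0.48 for TAS14, -0.08 for LOC100316877, 0.38 for LOC101250107, 0.29 for LOC101244293, -0.16 for PRO2, -0.40 for HKT1;2, -0.23 for LOC101263995.

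At 8 h LOC101258237 (STAY-GREEN-like) was higher in Micro-TOM-EX at 14.5 ± 6.91 against 0.08 ± 0.0346 FPKM (n = 3) and the flavonoid 3'-monooxygenase-like LOC101245978 at 10.7 ± 3.33 against 0.08 ± 0.0173. The defensin-like DEFL1 (chromosome 7) and the pathogenesis-related protein PR1b1, on an unplaced scaffold, both linked to defence, stood at 395 ± 63.4 against 38.4 ± 6.83 and at 581 ± 230.0 against 67.2 ± 33. LOC101255210 (chromosome 7) stood at 11.1 ± 0.838 against 0.467 ± 0.2. Lower were SODCP.2 at 7.62 ± 1.68 against 87.3 ± 22.5 and LOC101262189 at 1.95 ± 0.17 against 26 ± 5.77. The transcription factor MYB82 (LOC101268880, chromosome 7) stood at 1.75 ± 1.12 against 17.3 ± 4.54. The receptor-like kinase LOC101258158 (chromosome 6) stood at 0.227 ± 0.00577 against 6.87 ± 0.482 and the RABE1c gene LOC101250995 (chromosome 6) at 0.0833 ± 0.104 against 5.36 ± 0.685. These 10 log2 differences lay between -3.34 and 3.75 (SE 0.10 to 0.75, limma adjusted p from 1.9e-10 to 0.031). SODCP.2 had adjusted p = 0.06 to 0.13 without any 1 of 5 libraries, and 0.051 with a pseudocount of 0.1 and 0.073 with a block within each hour. PR1b1 had adjusted p = 0.064 without MT8r2.

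In all 307 genes differed, 182 higher and 125 lower in Micro-TOM-EX, while the authors' deposited table held 622 with q under 0.05. Without MT8r3 166 were higher and 175 lower, so the majority turned. The count was 188 without MT8r2, 163 in a fit of the 8 h libraries alone and 462 without the r2 pair, which enter only the shared spread. Of 208 cytosolic ribosomal proteins 1 was higher, the P3-like LOC101246068 at 129 ± 2.62 against 46 ± 8.75 FPKM, none was lower and 207 did not pass (1 and 0 adjusted over the list alone, median log2 difference 0.11, camera adjusted p = 0.00012, 0.98 with estimated correlation). Of 39 glutathione S-transferases none passed limma (0 adjusted over the list alone), 6 had an unadjusted p under 0.05 and 1 a q under 0.05 in the authors' deposited table, with a median of 0.14 (adjusted p = 0.023, 0.98 estimated). That list had adjusted p = 0.051 without MT8r1, 0.88 without EX8r3, and 1, 4, 4 and 1 lists passed without MT8r1, EX8r1, EX8r2 and EX8r3. The late embryogenesis abundant list passed without the r2 pair (0.042). None of the core salt genes passed limma, with 0.02 for TAS14, 0.33 for LOC100316877, 0.24 for LOC101250107, 0.21 for LOC101244293, 0.02 for PRO2, 0.01 for HKT1;2, 0.19 for LOC101263995, and NCED5 (LOC100316877) had adjusted p = 0.016 with a pseudocount of 0.1.

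Genes that differed between the materials in the same direction at all 3 hours numbered 70, 46 higher and 24 lower in Micro-TOM-EX, where independent lists would share 0.221 and 0.193. LOC101262189 (RABH1e-like) was lower at each hour, by -5.17, -3.79 and -3.17 log2 at 0, 2 and 8 h, and IBH1 (LOC109119046) was higher, by 2.22, 2.34 and 1.72. Glb1 was not among the 70, since it did not pass at 8 h (3.88 log2, limma adjusted p = 0.07, and 5.8e-06 without the r2 pair, 0.0082 in a fit of the 8 h libraries alone, 0.041 with a pseudocount of 0.1). By the positions in the deposited table, 17 of the 70 lay on chromosome 7 and 23 on chromosome 12, 57.1% together, where 14.1% of the tested genes lay. The count was 17 when each hour was fitted alone and 28 with a difference of at least 2-fold at each hour. From 2 h to 8 h 102 genes were higher at both hours (11.3 for independent lists), 62 lower (9.35) and 5 opposite.

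**Figure D4:**
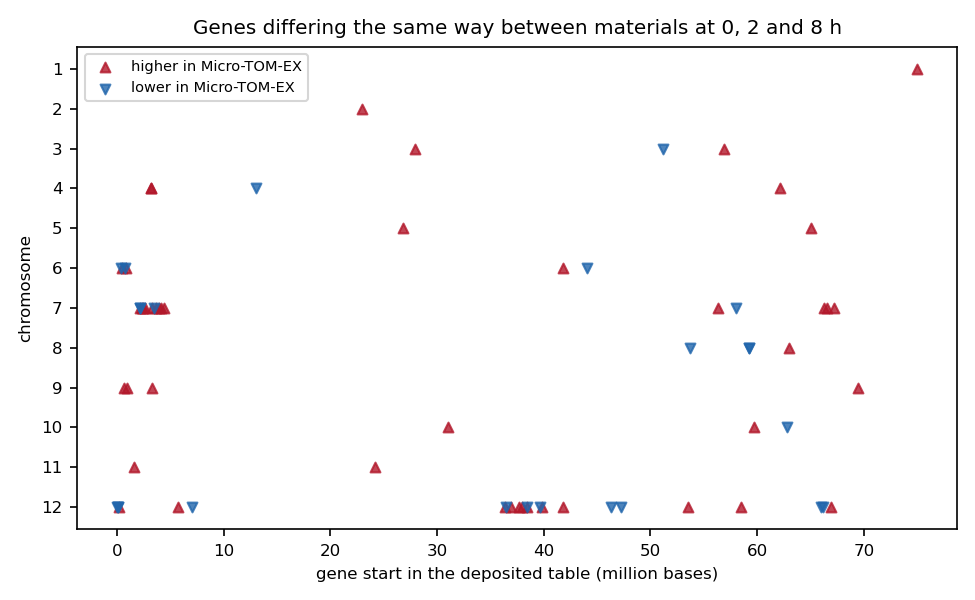
Start positions, in Mb, of the 70 genes that differed between the materials at 0, 2 and 8 h, by chromosome, with marks up for higher and down for lower in Micro-TOM-EX.

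**Figure D5:**
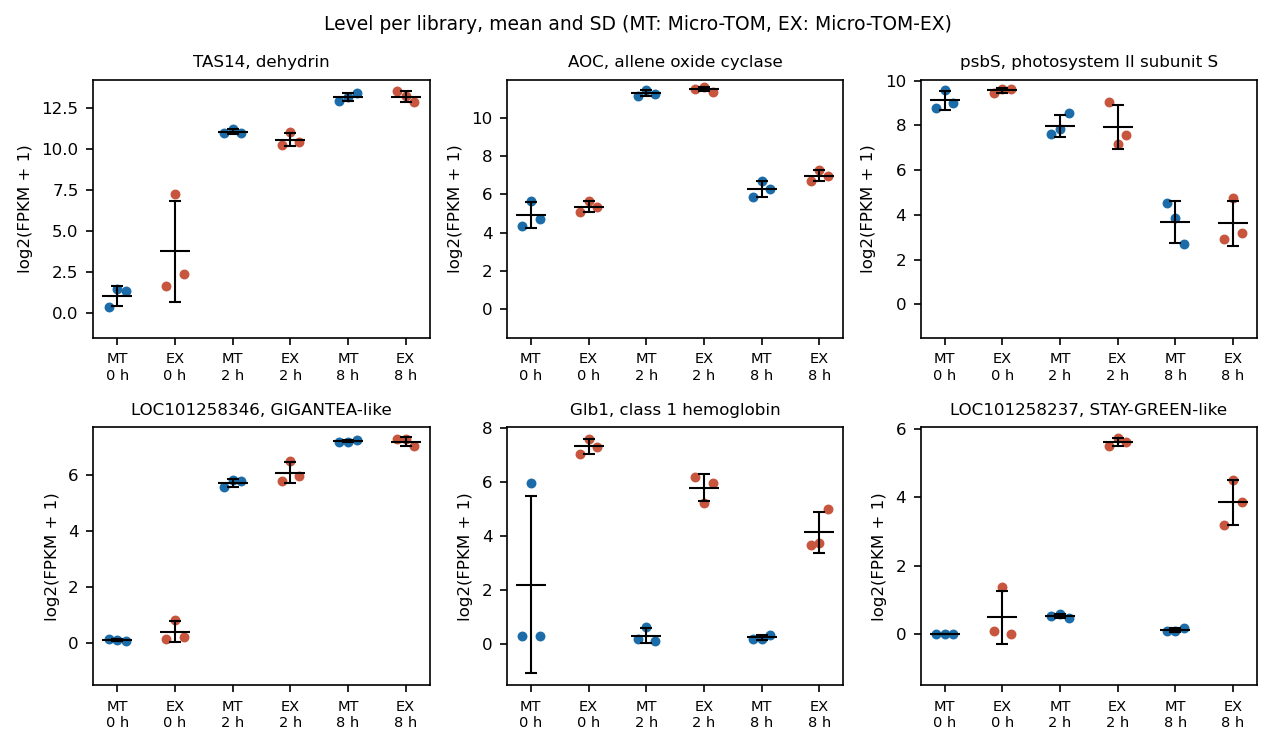
Log2(FPKM + 1) of TAS14, AOC, psbS, LOC101258346, Glb1 and LOC101258237 by group, 1 point per library with the mean and SD of each group of 3. A Micro-TOM library of 0 h (61.8 FPKM of Glb1) lies near those of Micro-TOM-EX.

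The test of the difference between the materials in their 2 h response asked which genes changed more, or in another direction, in one of them. LOC101258237 (STAY-GREEN-like) was listed at 0 in all Micro-TOM libraries of 0 h and at 0.43 ± 0.06 FPKM at 2 h, and went from 0.553 ± 0.907 to 48.5 ± 4.17 in Micro-TOM-EX (n = 3). The cellulose synthase-like E6 gene LOC101268453 stood at 5.42 ± 0.559 and 0.717 ± 0.103 in MT against 8.59 ± 0.665 and 44.4 ± 6.1 in EX at 0 and 2 h. LOC101244810 stood at 0.0467 ± 0.0451 and 0.437 ± 0.0764 in MT against 0.51 ± 0.213 and 33.5 ± 12 in EX. CMPG1 stood at 1.04 ± 1.38 and 0.883 ± 0.0462 in MT against 3.1 ± 1.12 and 35 ± 8.01 in EX. LOC101247596 (cellulose synthase-like D3) stood at 125 ± 102 and 19.1 ± 1.98 in MT against 7.39 ± 2.74 and 28.7 ± 4.15 in EX, and its 3 MT libraries of 0 h held 36.28, 235.84 and 101.98. The receptor-like kinase LOC101268564 rose less in EX, at 0.0167 ± 0.0289 and 55.2 ± 15.7 in MT against 0.04 ± 0.0529 and 5.04 ± 3.13 in EX. So did the MADS-box gene LOC101244319, at 0.213 ± 0.105 and 22.4 ± 7.94 in MT against 0.22 ± 0.22 and 2.02 ± 1.29 in EX. The 1-aminocyclopropane-1-carboxylate oxidase homologue LOC101245991 stood at 4.12 ± 0.78 and 6.51 ± 4 in MT against 7.59 ± 1.95 and 0.403 ± 0.107 in EX. The dicyanin precursor LOC543645 stood at 8.01 ± 4.72 and 449.5 ± 142 in MT against 26.5 ± 10.2 and 209 ± 144 in EX. The oil body-associated LOC101259110 stood at 0.433 ± 0.43 and 12.4 ± 1.12 in MT against 0.943 ± 0.595 and 1.36 ± 0.256 in EX. These 10 differences of log2 changes lay between -3.33 and 4.62 (SE 0.20 to 0.66, limma adjusted p from 2e-08 to 0.012), and CMPG1 had adjusted p = 0.062 with a pseudocount of 0.1.

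In all 1194 genes passed, 505 with a higher and 689 with a lower change in Micro-TOM-EX. After rescaling 673 were higher and 606 lower, so the majority turned. The count was 727 without MT2r1 and 693 without EX2r3. Of 54 DNA replication and histone genes, 0 had a higher change, 5 a lower one and 49 did not pass (median log2 -0.36, camera adjusted p = 0.014, 0.87 with estimated correlation). The histone LOC101252186 stood at 0.593 ± 0.412 and 8.22 ± 2.44 in MT against 1.29 ± 0.154 and 2.4 ± 0.251 in EX. The others, named after their values were seen, were LOC101262690, H2B-2, LOC101244346 and the cyclin LOC101261801. H2B-2 had adjusted p = 0.055 to 0.069 without any 1 of 4 libraries. The histone list had adjusted p = 0.24 without EX0r2, and 4, 2, 2, 3 and 3 lists passed without MT0r1, MT0r3, MT2r2, EX2r1 and EX2r2, and 3 without the r2 pair, among them the cytosolic ribosomal (0.0013) and clock lists (0.032). Of the core salt genes NCED5 (LOC100316877) passed, at 4.87 ± 0.706 and 12.1 ± 1.53 in MT against 8.93 ± 1.23 and 11.4 ± 0.918 in EX, with a difference of -0.84 log2 (adjusted p = 0.012). The others did not, with -3.20 for TAS14, 0.27 for LOC101250107, -0.30 for LOC101244293, -0.17 for PRO2, -0.59 for HKT1;2, -0.24 for LOC101263995, and TAS14 had -1.45 without EX0r2 (adjusted p = 0.067) and -1.65 without the r2 pair (0.044).

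At 8 h the glycine-rich RNA-binding protein gene LOC101262262 fell in Micro-TOM and not in Micro-TOM-EX, at 0 and 8 h standing at 978 ± 107 and 119 ± 12.1 in MT against 287 ± 11.9 and 435 ± 66.4 in EX (FPKM, n = 3). LOC101247596 stood at 125 ± 102 and 2.96 ± 0.262 in MT against 7.39 ± 2.74 and 3.28 ± 0.497 in EX. The peroxidase LOC101246783 stood at 51.1 ± 10.5 and 5.8 ± 2.42 in MT against 12.8 ± 4.17 and 14.3 ± 6.88 in EX. The wound-induced LOC101251891 stood at 249 ± 53 and 111 ± 28.1 in MT against 103 ± 16 and 366 ± 109 in EX. LOC101258237 was listed at 0 in MT at 0 h and at 0.08 ± 0.0346 at 8 h, against 0.553 ± 0.907 and 14.5 ± 6.91 in EX. With a lower change in EX stood the receptor-like kinase LOC101258158 at 0.06 ± 0.0436 and 6.87 ± 0.482 in MT against 0.46 ± 0.0557 and 0.227 ± 0.00577 in EX. MYB82 (LOC101268880) stood at 8.08 ± 3.06 and 17.3 ± 4.54 in MT against 8.45 ± 2.27 and 1.75 ± 1.12 in EX. The agmatine coumaroyltransferase-like LOC101244961 stood at 2.31 ± 0.353 and 111 ± 18 in MT against 2.84 ± 1.69 and 18.9 ± 4.95 in EX. DDTFR18 stood at 2.39 ± 0.704 and 45.8 ± 3.24 in MT against 19.7 ± 3.18 and 49.7 ± 3.35 in EX. The EIN3-binding F-box gene LOC101248690, of a family that restrains ethylene signalling, stood at 23.9 ± 1.38 and 154 ± 39.2 in MT against 33.3 ± 2.27 and 61 ± 21.9 in EX. These 10 differences of log2 changes lay between -3.14 and 3.69 (SE 0.13 to 0.61, limma adjusted p from 3.2e-09 to 0.022). LOC101244961 had adjusted p = 0.051 to 0.061 without any 1 of 3 libraries, and 0.054 to 0.087 with a pseudocount of 0.1, without the r2 pair and with a block within each hour.

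In all 249 genes passed, 150 with a higher and 99 with a lower change in Micro-TOM-EX (198 and 76 after rescaling). The count was 120 in a fit of the 4 groups alone. It was 151 without MT0r3, 153 without MT8r1, 131 without MT8r2, 133 without EX0r3, 120 without EX8r1 and 159 without EX8r2.

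Of 52 WRKY factors none passed limma (5 had a higher change adjusted over the list alone, and 10 higher and 2 lower an unadjusted p under 0.05), with a median difference of 0.18 (camera adjusted p = 0.00014, 0.54 with estimated correlation). Of 54 DNA replication and histone genes, 0 had a higher change, 1 a lower one and 53 did not pass (median log2 -0.39, adjusted p = 0.00014, 0.84 estimated), this being LOC101252186. Of 53 heat shock proteins, 0 had a higher change, 2 a lower one and 51 did not pass (0 and 5 adjusted over the list alone, median log2 -0.28, adjusted p = 0.009, 0.54 estimated). These were LOC101247772, at 43.9 ± 4.07 and 401 ± 122 in MT against 59.1 ± 4.04 and 237 ± 32.5 in EX, and Hsp90-1. Of 27 clock genes, 0 had a higher change, 1 a lower one and 26 did not pass (0 and 3 adjusted over the list alone, median log2 -0.24, adjusted p = 0.026, 0.54 estimated), this being APRR5 (LOC101256648). Of 83 AP2/ERF factors, 2 had a higher change, 2 a lower one and 79 did not pass (3 and 2 adjusted over the list alone, median log2 0.13, adjusted p = 0.04, 0.54 estimated). These were DREB3 and LOC101248897, and LOC101246590 and LOC101261693, and LOC101246590 was listed at 0 in Micro-TOM at 8 h. Of 81 auxin response genes, 0 had a higher change, 1 a lower one and 80 did not pass (median log2 -0.26, adjusted p = 0.049, 0.84 estimated), this being LOC101252930. Of 10 proline metabolism genes none passed limma (2 higher adjusted over the list alone, 3 with an unadjusted p under 0.05), with a median of 0.12 (adjusted p = 0.049, 0.54 estimated).

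These calls of 9 genes were not stable. Leaving out 1 library ended that of LOC101252186 with 9 of the 12 libraries (adjusted p from 0.06 to 0.11), LOC101247772 with 9 (0.056 to 0.12), LOC101261693 with 9 (0.052 to 0.13), LOC101248897 with 10 (0.057 to 0.13) and Hsp90-1 with 6 (0.056 to 0.075). A fit of the 4 groups alone ended 8 of the 9 (from 0.057 to 0.11), all but LOC101246590. A pseudocount of 0.1 ended 6 (from 0.052 to 0.83), all but Hsp90-1, DREB3 and LOC101248897. Without the r2 pair 5 did not pass (from 0.05 to 0.13), LOC101252186, LOC101247772, Hsp90-1, LOC101248897 and LOC101261693, and without a filter the same but Hsp90-1 (from 0.054 to 0.069). After rescaling LOC101247772 did not (0.11). With the replicate number as a block LOC101252186 (0.06) and LOC101261693 (0.056) did not pass, nor did proline and auxin (both 0.051). With a block within each hour APRR5 (LOC101256648), LOC101248897, LOC101261693 and LOC101252930 did not (from 0.051 to 0.063). Among the lists, adjusted p for proline was 0.06 to 0.18 without any 1 of 7 libraries. For auxin it was 0.072 to 0.12 without any 1 of 6 libraries. For AP2/ERF it was 0.061 to 0.32 without any 1 of 5 libraries and 0.13 after rescaling, and for the clock 0.072 without MT8r2, 0.061 without EX0r1. Without the r2 pair proline (0.19), AP2/ERF (0.44) and auxin (0.069) no longer passed, and the photosystem (0.0027) and cytosolic ribosomal lists (0.0024) did. Without MT8r1 4 lists passed, and after rescaling the photosystem proteins passed (0.025, 0.18 before). None of the core salt genes passed limma, with -2.69 for TAS14, -0.43 for LOC100316877, 0.13 for LOC101250107, -0.37 for LOC101244293, 0.01 for PRO2, -0.18 for HKT1;2, 0.19 for LOC101263995, and TAS14 had -0.94 without EX0r2.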

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

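The differences between the materials in their response were planned tests, and the tests of the 3 patterns weighed afterwards were chosen after the results were seen. The difference in the 2 h response passed limma for 1194 genes. Among genes with a descriptive name its largest values were 4.62 log2 for LOC101258237, 4.15 for LOC101247596, 4.14 for LOC101268453, 4 for LOC101244810 and 3.06 for CMPG1. On the lower side they were -3.33 for LOC101268564, -3.04 for LOC101245991, -2.98 for LOC543645, -2.98 for LOC101244319 and -2.95 for LOC101259110, and the median of DNA replication and histones was -0.36. The difference in the 8 h response passed for 249 genes, led among those with such a name by LOC101247596 (3.69), LOC101262262 (3.61), LOC101258237 (3.26), LOC101246783 (3.05) and LOC101251891 (2.96). Lowest were LOC101258158 (-3.14), LOC101268880 (-2.88), LOC101244961 (-2.64), DDTFR18 (-2.50) and LOC101248690 (-1.81). Uncharacterized genes, named after their values were seen, reached -3.95 at 2 h (LOC101248555) and -3.16 at 8 h (LOC101247111). List medians at 8 h were 0.12 for proline metabolism, -0.28 for heat shock proteins, 0.13 for AP2/ERF factors, 0.18 for WRKY factors, -0.26 for auxin response, -0.24 for the circadian clock and -0.39 for DNA replication and histones. Samples far from the others were not sought by test in groups of 3.

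With 10 splits per pair of groups, the true split had the most genes (1 of 10) in each comparison of hours, where another split reached at most 1 gene, and between the materials at 0 h (at most 2 genes), 2 h (7) and 8 h (78), and 10 splits are too few for a share under 0.05. The 2 h difference of responses had 1194 genes, and 3 of 100 splits reached that many, the highest other 1425. The 5 highest others exchanged all 6 libraries of 2 h, which keeps the true grouping of that hour, so they hold real differences of the materials as well as chance. The 8 h difference had 249, reached by 1 of 100 (highest other 194, and 4 of the 5 highest kept the true grouping of 0 h), and the 70 genes of all 3 hours were reached by 1 of 100 (highest other 0). For gene lists the number of splits that reached the true count was 5, 1, 4 and 5 of 10 for the 4 comparisons of hours (Micro-TOM 2 h and 8 h, Micro-TOM-EX 2 h and 8 h) and 10, 9 and 10 of 10 between the materials at 0, 2 and 8 h. It was 98 of 100 and 32 of 100 for the 2 h and 8 h differences of responses. In the same order other splits reached up to 14, 10, 16, 13, 8, 5, 12, 8 and 14 lists. Chance was not excluded for any set of lists but Micro-TOM 8 h, where 10 splits are too few.

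In MT 0 h replicate 2 Glb1 stood at 61.8 FPKM against 0.24 and 0.24 in the other libraries of its group. Over 7 transcripts of Micro-TOM-EX the median share of that material in this library was 0.33, and over 6 transcripts of Micro-TOM 0.41, where other libraries of 0 h had medians from -0.23 to 0.19, which fits a mixed sample with part of its RNA from Micro-TOM-EX (the smaller median, 0.33). A median share of 0.34 over both argues against a wholly mislabelled library. A plant carrying both sets of alleles could not be told apart (upper quartile 0.4). Against a mixture stood 2 new gene models of 1 locus at -1.58 and -0.51 (with the locus counted once, the median over 5 loci was 0.42), and a stricter choice of genes, 1 of 2 tried, left 3 transcripts of Micro-TOM-EX at 0.34 and 1 of Micro-TOM, a model of that locus, at -1.58.

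In EX 0 h replicate 2 stress transcripts were raised, with TAS14 at 152.43 FPKM against 2.15 and 4.14, and CHI3 at 668.01 against 24.26 and 22.68. Over 68 genes they stood at a median of 2.03% of the 8 h mean (10th to 90th percentile 0.657 to 10.4), against 0.295% in the other 0 h libraries. The spread of that share was 1.92 times the largest spread between 2 replicates of 8 h and 3.06 times the smallest, so whether part of the RNA came from an 8 h library could not be told, and a first form with 1 pair of replicates argued against it. A share from 2 h was argued against (4.38 times, 49 genes), as was a library of another hour (lowest correlation with its own group 0.969, highest with 2 h or 8 h 0.761). A response of the plants themselves before treatment was not tested.

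The 70 genes of all 3 hours gathered on chromosomes 7 (17) and 12 (23). Those 2 chromosomes ranked first from the 159 genes of 0 h and 2 h, and of 233 other genes of 8 h 93 lay on them (39.9% against 13.5%, odds ratio 4.25, one-sided Fisher exact p = 4.1e-23), which fits segments that differ between the materials. Placement by chance along each chromosome was argued against, as the median distance to the nearest other of 69 loci was 284.2 kb against 849.1 at random (permutation p = 1e-04, the smallest that 10000 draws allow). Reads of Micro-TOM-EX alone lost in mapping were argued against as the sole cause, since 15 of 40 genes (37.5%, 95% interval 22.7 to 54.2) were lower in it. That form was set after the directions were counted, and losses in either material, gene by gene, stay possible.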

How the results depend on the processing

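Leaving out 1 library at a time gave, in numbers of genes, 12964 to 13545 for Micro-TOM 2 h, 12278 to 12543 for Micro-TOM 8 h, 13260 to 13805 for Micro-TOM-EX 2 h, 12315 to 12692 for Micro-TOM-EX 8 h, 420 to 758 for the materials at 0 h, 1259 to 3049 for them at 2 h, 188 to 341 for them at 8 h, 693 to 1468 for the 2 h difference of responses and 120 to 365 for the 8 h difference. The genes of all 3 hours then numbered 51 to 100, and r between the responses was 0.932 to 0.941 at 2 h and 0.948 to 0.961 at 8 h. The gene lists called were 11 to 12 for Micro-TOM 2 h, 10 to 12 for Micro-TOM 8 h, 11 to 15 for Micro-TOM-EX 2 h, 10 to 11 for Micro-TOM-EX 8 h, 1 to 8 for the materials at 0 h, 0 to 2 for them at 2 h, 1 to 4 for them at 8 h, 1 to 4 for the 2 h difference of responses and 4 to 9 for the 8 h difference.

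A 2-fold minimum, which tests for less by its construction, left 7808 for Micro-TOM 2 h, 6895 for Micro-TOM 8 h, 8137 for Micro-TOM-EX 2 h, 7041 for Micro-TOM-EX 8 h, 304 for the materials at 0 h, 621 for them at 2 h, 156 for them at 8 h and 739 for the 2 h difference of responses, and 28 genes of all 3 hours. A fit of the compared groups alone gave 104 genes at 0 h (738 before), 1867 at 2 h (2522) and 163 at 8 h (307). It gave 120 for the 8 h difference and 17 for all 3 hours. A pseudocount of 0.1 gave 165 for the 8 h difference and r = 0.927 at 2 h. Without the r2 pair, chosen after seeing the data, 462 genes passed between the materials at 8 h, and 5 lists at 0 h and 3 for the 2 h difference. The authors' deposited table gave 622 genes at 8 h. Causes were not tested beyond the 2-fold minimum.

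With an estimated correlation camera called 0 lists in all 9 comparisons. Fry called 27 for Micro-TOM 2 h, 27 for Micro-TOM 8 h, 26 for Micro-TOM-EX 2 h, 25 for Micro-TOM-EX 8 h, 0 for the materials at 0 h, 0 for them at 8 h, 3 for the 2 h difference of responses and 1 for the 8 h difference, and the cause was not tested. The other summaries stayed within 1.5 times their value.

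Of the genes named, 3756 values under the alternatives kept direction and side of the threshold, 208 no longer passed (122 with a library left out, 28 in a fit of the compared groups alone), 9 passed only then and 37 changed sign, most of them near 0. In MT 2 h these were HsfA1a 0.08 rescaled, LOC101244293 0.20 rescaled, 0.32 block within hours, 0.07 without both number 2 libraries of 0 h and -0.32 to 0.07 without 1 library, PRO2 -0.04 to 0.06 without 1 library. In MT 8 h these were LOC101263995 0.17 block within hours. In EX 2 h these were HsfA1a 0.04 rescaled, LOC101244293 0.03 block within hours, PRO2 0.27 rescaled (which passed). In EX 8 h these were LOC101263995 -0.07 to 0.24 without 1 library. In the materials at 0 h these were PRO2 -0.05 rescaled and 0.00 to 0.02 without 1 library, LOC101263995 -0.03 rescaled, -0.03 without both number 2 libraries of 0 h and -0.05 to 0.05 without 1 library. In the materials at 8 h these were TAS14 -0.15 to 0.20 without 1 library, PRO2 -0.02 to 0.06 without 1 library, HKT1;2 -0.02 pseudocount 0.1 and -0.18 to 0.22 without 1 library, LOC101263995 -0.01 to 0.30 without 1 library. In the 8 h difference these were LOC100316877 0.03 pseudocount 0.1, PRO2 0.00 without both number 2 libraries of 0 h and -0.03 to 0.05 without 1 library, HKT1;2 -0.37 to 0.04 without 1 library, LOC101263995 -0.01 to 0.30 without 1 library. The cause of these changes of sign was not tested.

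DESeq2's test, TMM scaling against size factors, transcripts in place of genes, and FPKM beside counts were not run, as no counts or transcripts were used here. FPKM rounded to 2 decimals limits genes near 0, where a value of 0.01 is the smallest step.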

Other observations

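The comparison of 8 h with 2 h within each material was chosen after the data were seen, as were the genes named for it and the test of pathways that follows. By 8 h several early transcripts had gone down again. In Micro-TOM and Micro-TOM-EX, allene oxide synthase (aos) changed by -6.07 and -5.79 log2 between 2 h and 8 h, allene oxide cyclase (AOC) by -4.99 and -4.52, and hsc70 by -5.05 and -5.08. GIGANTEA (LOC101255788) rose by 3.97 and 4.32, and the ribonuclease RNALE by 4.74 and 4.12. The materials differed in 3 of the 12 genes looked at: galactinol synthase 2 (GolS2) changed by -3.17 log2 in Micro-TOM and -1.61 in Micro-TOM-EX (limma adjusted p of the difference = 0.018), HSP90 by -2.07 and -3.56 (adjusted p = 0.019) and the AP2/ERF gene LOC104645451 by -4.03 and -5.47 (adjusted p = 0.00084).

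In all 12837 genes changed from 2 h to 8 h in Micro-TOM (8472 higher, 4365 lower) and 12693 in Micro-TOM-EX (8336 and 4357), and 353 differed between the materials (233 and 120). Rescaling moved these log2 changes by -0.37 and -0.36 and gave 5900 higher and 6381 lower in Micro-TOM and 5871 and 6335 in Micro-TOM-EX, so the direction of the majority turned. Of 83 AP2/ERF factors 14 rose and 53 fell in Micro-TOM (camera adjusted p = 5.1e-09, and 0.038 with an estimated correlation), and 14 and 54 in Micro-TOM-EX (adjusted p = 9.7e-09, and 0.043 with an estimated correlation). Of 37 proteasome subunits 35 rose and 0 fell in Micro-TOM (adjusted p = 1.3e-06, and 0.22 with an estimated correlation), and 35 and 1 in Micro-TOM-EX.

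Over 116 KEGG pathways and 12 comparisons, camera made 21 calls, none of which held with an estimated correlation (adjusted p of 0.11 or more). At 8 h the citrate cycle rose in Micro-TOM (43 of 77 genes up and 13 down, adjusted p = 0.021) and Micro-TOM-EX (45 and 18, adjusted p = 0.022), as did arachidonic acid metabolism, propanoate metabolism and the proteasome in both. Photosynthesis fell in all 4 comparisons with 0 h (adjusted p from 2.6e-06 to 0.0024), and flavonoid synthesis rose at 2 h in both (0.0019 and 0.0087). Between the materials benzoxazinoid synthesis alone was called, at 8 h (5 of 16 higher, adjusted p = 0.0036).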
